A study of Plasmodium falciparum with 30 samples.

How the data were processed

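The series holds 30 samples, of which 9 are RNA libraries (3 per stage), 15 are RNAPII ChIP samples and 6 are input DNA samples, grouped by the stage, antibody and replicate in their titles. RNA libraries were made with a stranded mRNA kit and ChIP libraries with a DNA library kit, per the labels' protocols. Replicates of RNA are biological per the series text, and what makes them separate cultures is not given.

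The RNA file holds whole-number counts per gene that the authors deposited without normalization. STAR 2.5.1b, HTSeq 0.6.1p1 and Trim Galore 0.4.1 are named in the submitters' processing notes, while the counting mode, strand setting and genome build are not given in the sources used here. The table has 5772 features. Of these 170 are splice variants with a suffixed ID, and 126 of those have 0 counts in every library. Near-identical genes (FP2A and FP2B, HRP2 and HRP3) may share or lose reads in such counting and their values are uncertain to that extent, as are genes that overlap on the opposite strand. Of the IDs, 5557 matched a locus tag of the RefSeq gene table used here, which gives no symbol other than the locus tag for any of them. The files pair no ID with a name. The names printed are those fixed with the gene lists before the data were examined, from general knowledge of the ID, and were not checked against an annotation here, and genes outside the lists are given by ID.

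Peak lists were called with MACS2 2.1.1.20160309 on paired-end fragments at a p threshold of 0.05, with 1 duplicate kept and input DNA of the same stage as control, per the file headers. Each N20, CTD and Ser5-P list comes from a single library. For Ser2/5-P, 2 samples per stage carry the label, and which of them gave the list is not stated. Fold enrichment over input is a linear ratio per peak that the authors deposited, and it was used to describe and rank peaks within a list. The −log10 of p and q per peak are the authors' values, and the lists hold q values although the file headers say that none were calculated. For the Ser2/5-P lists peaks were ranked by q. Bowtie2 2.2.6 is named in the submitters' processing notes. Input depths per the file headers were 1446678 fragments for rings, 3824948 for trophozoites and 2493516 for schizonts. Summit and narrow peak files repeat the same peaks and were not used.

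Genes were kept with edgeR's filterByExpr (5029 kept), scaled with TMM and tested with edgeR 4.0.16 quasi-likelihood tests on all 9 libraries in R 4.3.3, with stage as the term and no replicate block, for the 3 pairs of stages and for any difference between the 3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a positive log2 fold change means higher in the later stage. CPM are scaled by TMM, with mean factors of 0.722 in rings, 1.1 in trophozoites and 1.26 in schizonts. The biological coefficient of variation was 0.152. The 10 most abundant genes took 12.8% of counts in rings, 11.7% in trophozoites and 9.8% in schizonts on average. Replicates of a stage differed by far more than sampling noise (chi-square per degree of freedom between 7.99 and 233), so none is a copy of another, and schizont replicates 1 and 3 differed most.

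Gene lists fixed beforehand were exported proteins and host cell remodelling, haemoglobin digestion, glycolysis, DNA replication, merozoite invasion and egress, and gametocyte markers. They were tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, adjusted over 18 tests. Lists defined by a product description (ribosomal proteins, proteasome, surface antigen families and others) were not analysed because the gene table used here has no descriptions. Genes are named by a rule fixed beforehand. Per comparison it takes the 5 largest rises and falls at 2-fold or more, with libraries that do not overlap and at least 50 CPM in the higher stage, of which at most 2 each way are printed when they stand outside the lists. From each list it takes the passing members with the 2 highest mean levels and the passing member with the largest change. RPB1 is given at every stage. Surface antigen families could not be left out as the rule asked, since no descriptions were at hand, and in place of 3 genes per stage with peaks of all antibodies the text gives regions. Other genes are marked where named.

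On simulated counts with 200 changed genes, the tests called 96% of genes changed 2-fold and 99% of those changed 4-fold between trophozoite and ring, with 5 of 4829 unchanged genes called. For schizont against trophozoite these were 96% and 100% with 8 of 4829, and for schizont against ring 95% and 99% with 7 of 4829. The simulation changed 200 of 5029 genes in random directions, with the same spread for every gene and no difference in composition between stages. In the data 79.6% to 90.3% of genes changed per comparison, so these rates do not cover errors that come from the scaling.

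Peak lists were compared by the share of peaks overlapping by at least 1 bp, with Wilson 95% intervals, beside 100 random placements within the chromosomes, with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. On 1000 simulated peaks the overlap code missed the planted share by 0.0 percentage points. Alternatives fixed beforehand were other size factors, DESeq2 1.42.0, no filter, a replicate block, each library left out, the 10 most abundant genes left out, fits of 6 libraries, a 2-fold limit, q below 0.01, the 1000 best peaks, an overlap of 50% of the shorter peak and summits within 200 bp. Scaling by library size alone and overlaps without peaks of 5-fold or more were added after the data were seen, as were the limit of 5-fold for tall peaks and the 60 kb window at chromosome ends. The alternative with 50% of the shorter peak used 5 random placements instead of 100. Per-gene RNAPII comparisons (summit position along genes, occupancy against mRNA, peaks in gene lists) need an annotation of the build of the peak lists and were not analysed here.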

Results

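The series profiled RNA polymerase II (RNAPII) and mRNA in Plasmodium falciparum, the malaria parasite of human red blood cells, in the strain labelled T996. Cultures synchronised with sorbitol were sampled at 3 stages of the cycle inside the red cell, which are the ring (young, after invasion), the trophozoite (growing) and the schizont (dividing into new merozoites). Polyadenylated RNA was sequenced from 3 libraries per stage, which the series describes as biological replicates. RNAPII was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with 4 antibodies. N20 recognises the N-terminus of the largest subunit RPB1, CTD its C-terminal domain, Ser5-P that domain phosphorylated at serine 5, and Ser2/5-P the form phosphorylated at serines 2 and 5. The count table held between 13155667 and 17290710 counts per RNA library over 5772 features, of which 5029 passed the filter on low counts and were tested. ChIP-seq was represented by 12 peak lists, 1 per antibody and stage, called from between 1035895 and 3968613 fragments, so differences between peak lists have no replicate check. The purpose given for the series was to map RNAPII and its phosphorylated forms and to relate them to mRNA.

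The mRNA population was remodelled between all stages. Of 5029 genes, 4834 (96.1%) changed across the 3 stages (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p below 0.05), and their highest mean lay in rings for 1944, in trophozoites for 894 and in schizonts for 1996. RPB1 (PF3D7_0318200), the largest subunit of RNAPII and the protein all 4 antibodies recognise, fell from 1338 ± 116 CPM (counts scaled by library size and composition; SD, n = 3) in rings to 689 ± 86.9 in trophozoites and 439 ± 77.1 in schizonts. Its log2 fold change was -0.96 (SE 0.15, adjusted p = 9.48e-05) from ring to trophozoite and -0.65 (SE 0.15, adjusted p = 0.00181) from trophozoite to schizont. Scaled by library size alone, the fall of RPB1 from ring to trophozoite was -0.345 with adjusted p = 0.0833.

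Compared with rings, trophozoites had less mRNA of proteins exported into the red cell and more of the DNA replication machinery. Of 16 tested genes of exported and host cell remodelling proteins, 11 fell, 3 rose and 2 did not pass, with a median log2 fold change of -3.76 (13.6-fold lower). HRP2 (PF3D7_0831800), a histidine-rich secreted protein used in rapid diagnostic tests, fell from 24100 ± 2350 to 1180 ± 139 CPM (n = 3 each), and the heat shock protein HSP70x (PF3D7_0831700) fell from 18700 ± 586 to 2080 ± 162 CPM. MAHRP1 (PF3D7_1370300), a protein of the Maurer's clefts that sort exported cargo, fell 48.9-fold, with a log2 fold change of -5.61 (SE 0.17, adjusted p = 4.94e-10). The 3 members that rose were EXP2 (PF3D7_1471100, log2 fold change 1.00), the pore of the membrane around the parasite, MESA (PF3D7_0500800, 1.74, from 1424 ± 375 to 4759 ± 2410 CPM) and GBP130 (PF3D7_1016300, 0.87), all named after their values were seen.

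Of 19 tested replication genes, 18 rose and 1 fell from ring to trophozoite, with a median log2 fold change of 2.93 (7.62-fold higher). PCNA1 (PF3D7_1361900), the sliding clamp of DNA polymerase, rose from 95.9 ± 4.3 to 950 ± 71.4 CPM, MCM3 (PF3D7_0527000), a subunit of the replicative helicase, from 61.7 ± 3.72 to 586 ± 6.58 CPM, and the flap endonuclease FEN1 (PF3D7_0408500) from 4.83 ± 0.453 to 60.4 ± 2.84 CPM. The member that fell was the topoisomerase TOP2 (PF3D7_1433500), from 1059 ± 34.9 to 198 ± 15.2 CPM, named after its values were seen. Of 30 merozoite invasion and egress genes, 16 rose, 9 fell and 5 did not pass, with a median log2 fold change of 0.72. SERA5 (PF3D7_0207600), a protease-like protein of egress, rose from 68.9 ± 6.05 to 1080 ± 124 CPM, and the rhoptry protein RhopH3 (PF3D7_0905400) from 94.1 ± 10.6 to 567 ± 102 CPM.

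Of 13 haemoglobin digestion genes, 9 fell, 3 rose and 1 did not pass from ring to trophozoite (median log2 fold change -1.05). The aminopeptidase M1AAP (PF3D7_1311800) fell from 5330 ± 84.9 to 2500 ± 141 CPM and LAP (PF3D7_1446200) from 2260 ± 172 to 1500 ± 140 CPM, which by library size alone was a log2 fold change of 0.025 that did not pass. Haem detoxification protein HDP (PF3D7_1446800) rose from 16.4 ± 1.19 to 118 ± 3.32 CPM, and the 2 other members that rose were the plasmepsin PMII (PF3D7_1408000, log2 fold change 0.61) and the falcipain FP2A (PF3D7_1115700, 0.58), both named after their values were seen. Of 12 glycolysis genes, 7 fell and 5 did not pass with the main scaling (median log2 fold change -0.41), while by library size alone 6 rose and 3 fell, with a median of 0.21. Pyruvate kinase PYK (PF3D7_0626800) went from 8250 ± 467 to 6090 ± 489 CPM (log2 fold change -0.44, and 0.18 without a call by library size alone) and the mutase PGM1 (PF3D7_1120100) from 6080 ± 441 to 2600 ± 226 CPM.

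In all, 4227 of 5029 genes changed between trophozoite and ring, 2323 of them higher and 1904 lower in trophozoites, and 2910 by at least 2-fold. Of genes outside the lists, PF3D7_0623300 (16.6-fold) and PF3D7_0207700 (15.7-fold) were among the 5 largest rises, and PF3D7_0201700 (74.3-fold) and PF3D7_1002000 (74-fold) were the largest falls under the naming rule. Adjusted over the list alone, the same numbers of members passed in each of the 5 lists above. Against all other genes, camera with a preset correlation called the exported (adjusted p = 0.000348), haemoglobin (adjusted p = 0.0256) and glycolysis lists (adjusted p = 0.0373) lower and the replication list higher (adjusted p = 6.97e-05), and did not call the invasion list (adjusted p = 0.328). All 4 calls were lost, with adjusted p = 0.38, adjusted p = 0.442, adjusted p = 0.573 and adjusted p = 0.336 with an estimated correlation, and the glycolysis call was also lost without ring replicate 3 (adjusted p = 0.0532) and without trophozoite replicate 1 (adjusted p = 0.0741). By library size alone, the share of changed genes that were higher in trophozoites was 74.9% in place of 55% and the median of all genes moved by 0.61 on the log2 scale, so directions are relative to the library composition. The same scaling gave 5 higher and 10 lower exported, 4 higher and 7 lower haemoglobin, and 18 higher and 2 lower invasion genes.

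Compared with trophozoites, schizonts gained mRNA for merozoite invasion and lost mRNA for feeding and energy metabolism. Of 30 invasion and egress genes, 28 rose and 2 fell, with a median log2 fold change of 2.89 (7.39-fold higher). SERA5 rose from 1080 ± 124 to 10600 ± 497 CPM (n = 3 each), RhopH3 from 567 ± 102 to 5750 ± 581 CPM, and the merozoite surface protein MSP2 (PF3D7_0206800) from 205 ± 43.9 to 2250 ± 630 CPM, a log2 fold change of 3.46 (SE 0.22, adjusted p = 9.56e-08). The 2 that fell were the transcription factor AP2-I (PF3D7_1007700, log2 fold change -0.75) and the bromodomain protein BDP1 (PF3D7_1033700, -0.36), both known as regulators of invasion genes and both named after their values were seen. The fall of BDP1 was lost in 6 alternatives, among them without trophozoite replicate 2 (adjusted p = 0.0524), trophozoite replicate 3 (adjusted p = 0.0555) or schizont replicate 2 (adjusted p = 0.0555). Of 19 replication genes, 14 rose, 4 did not pass and 1 fell (median log2 fold change 0.81). MCM3 rose 2.85-fold, FEN1 3.61-fold and the large subunit of ribonucleotide reductase (PF3D7_1437200) 1.87-fold, and the member that fell was the DNA polymerase delta subunit POLD1 (PF3D7_1017000, log2 fold change -0.38), a fall that did not pass by library size alone and was named after its value was seen.

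Of 12 glycolysis genes, 11 fell and 1 did not pass from trophozoite to schizont (median log2 fold change -1.07, 2.09-fold lower). GAPDH (PF3D7_1462800) fell from 22600 ± 2670 to 10400 ± 2550 CPM, enolase ENO (PF3D7_1015900) from 14000 ± 1310 to 3330 ± 676 CPM and glucose-6-phosphate isomerase GPI (PF3D7_1436000) 4.71-fold. Of 13 haemoglobin digestion genes, 11 fell, 1 rose and 1 did not pass (median log2 fold change -1.26), with M1AAP falling 3.59-fold, LAP 1.97-fold and FP2A, a cysteine protease of the food vacuole, from 1420 ± 37.1 to 151 ± 23.9 CPM. The member that rose was another falcipain, FP3 (PF3D7_1115400, log2 fold change 0.70), named after its value was seen. Of 16 exported protein genes, 13 fell and 3 rose (median log2 fold change -1.30). HRP2 fell 3.34-fold and HSP70x 4.31-fold, whereas RESA (PF3D7_0102200), an antigen carried into the red cell by the invading merozoite, rose from 94.3 ± 14.3 to 1650 ± 171 CPM, the largest rise under the naming rule, by 4.13 on the log2 scale (SE 0.15, adjusted p = 8.48e-09). The other members that rose were PTP1 (PF3D7_0202200, 1.32) and ETRAMP2 (PF3D7_0202500, 0.92), named after their values were seen.

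Between schizont and trophozoite 4003 genes changed, 2042 higher and 1961 lower in schizonts, and 2466 changed by at least 2-fold. Of genes outside the lists, PF3D7_0805200 (16.3-fold) and PF3D7_1149200 (13.2-fold) were among the largest rises and PF3D7_0401500 (20.3-fold) and PF3D7_1478700 (19.4-fold) the largest falls under that rule. The counts adjusted over the list alone were the same as over all genes. Camera called the invasion (adjusted p = 1.41e-07) and replication lists (adjusted p = 0.00317) higher and the haemoglobin (adjusted p = 0.00185), glycolysis (adjusted p = 0.00202) and exported lists (adjusted p = 0.0207) lower. These calls were lost at adjusted p = 0.393, adjusted p = 0.38, adjusted p = 0.393, adjusted p = 0.427 and adjusted p = 0.393 with an estimated correlation.

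Schizonts and rings, the stages on either side of reinvasion, differed in more genes than the other pairs. With the main scaling, exported protein genes fell in 14 of 16 cases and none rose, with a median log2 fold change of -4.12 (17.4-fold lower). By library size alone 12 fell and 2 rose. MAHRP1 fell from 6510 ± 302 CPM in rings to 45.4 ± 9.12 in schizonts, HRP2 68.4-fold, HSP70x 38.8-fold and the histidine-rich protein HRP3 (PF3D7_1372200) from 19300 ± 2410 to 163 ± 28.6 CPM. Invasion and egress genes rose in 28 of 30 cases, with 1 fall and a median 8.02-fold rise. SERA5 rose 153-fold (log2 fold change 7.26, SE 0.16, adjusted p = 5.37e-11), its neighbour and relative SERA6 (PF3D7_0207500) 108-fold and RhopH3 61-fold, while BDP1 fell by 0.90 on the log2 scale, which did not pass by library size alone (adjusted p = 0.332) and was named after its value was seen. Replication genes rose in 18 of 19 cases (median log2 fold change 3.62), among them FEN1 at 45.1-fold, MCM3 at 27.1-fold and PCNA1 at 11.5-fold, and TOP2 again fell (-1.99), named after its value was seen.

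Haemoglobin digestion genes were lower in schizonts than in rings for 11 of 13 members (median log2 fold change -2.32), with M1AAP 7.64-fold, LAP 2.96-fold and the falcipain FP2B (PF3D7_1115300) 18.1-fold lower, and HDP (2.52) and FP3 (0.73) higher, these 2 named after their values were seen. Glycolysis genes fell in 11 of 12 cases (median log2 fold change -1.49), GAPDH by 2.17-fold, ENO by 4.74-fold and GPI by 7.18-fold. In total 4540 genes changed, 2367 higher and 2173 lower in schizonts, and 3748 by at least 2-fold. Outside the lists, PF3D7_0207700 (140-fold) and PF3D7_0715300 (125-fold) were among the largest rises, and PF3D7_1148700 (154-fold) and PF3D7_1301700 (125-fold) among the largest falls. The list counts were the same adjusted over the list alone. Camera gave adjusted p = 7.32e-05 for the exported, replication and invasion lists, adjusted p = 0.0033 for haemoglobin and adjusted p = 0.00203 for glycolysis. With the correlation estimated, the exported list had adjusted p = 0.378, replication adjusted p = 0.336, invasion and haemoglobin adjusted p = 0.393 and glycolysis adjusted p = 0.427 with an estimated correlation. By library size alone 64.4% of the changed genes were higher in schizonts, in place of 52.1%, and the median of all genes moved by 0.80. The same scaling gave 29 higher and 0 lower invasion genes and 2 higher and 9 lower glycolysis genes.

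**Figure D1:**
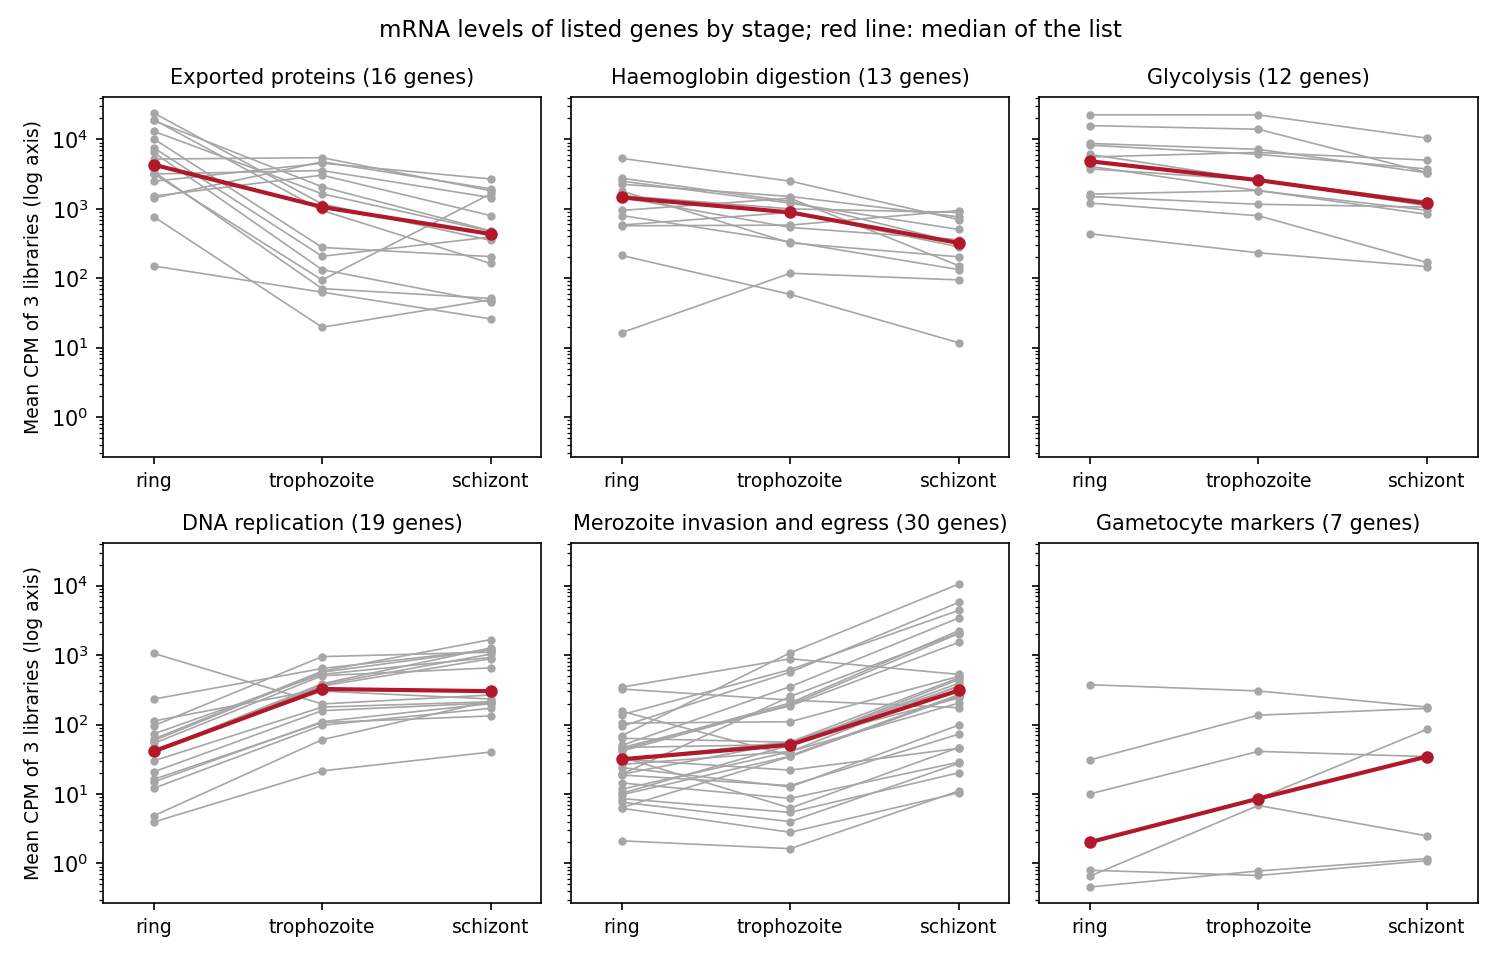
Mean mRNA level in CPM (vertical log axis, mean of 3 libraries) at the ring, trophozoite and schizont stage for the tested genes of 6 lists fixed beforehand; grey lines are single genes and the red line is the median of the list. The highest mean lies in rings for 11 of 16 exported protein genes, and in schizonts for 16 of 19 replication and 28 of 30 invasion genes.

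Markers of gametocytes, the sexual stages a blood culture can also hold, differed widely in level. Of 14 markers, 7 did not pass the filter, among them the sexual commitment regulators AP2-G (PF3D7_1222600), with 51 counts summed over the 9 libraries, and GDV1 (PF3D7_0935400), with 3. GDV1 and another untested marker, GEXP5 (PF3D7_0936600, 0 counts), lie in a block of chromosome 9 with almost no mRNA, described below. Their low counts are thus not particular to gametocyte markers. Among the 7 that were tested, 4 rose and none fell from ring to trophozoite, 1 rose and 2 fell from trophozoite to schizont, and 5 rose and 1 fell from ring to schizont, with the same counts adjusted over the list alone. These counts moved with the alternatives, for example to 4 higher and 2 lower for trophozoite against ring without schizont replicate 2, and to 3 higher and 3 lower for schizont against trophozoite without schizont replicate 1. MDV1 (PF3D7_1216500) rose from 2.02 ± 0.383 CPM in rings to 85.1 ± 17.1 in schizonts and G27/25 (PF3D7_1302100) from 30.8 ± 3.45 to 171 ± 41.4, whereas PFS16 (PF3D7_0406200) fell from 374 ± 28.5 to 178 ± 36.5. PFS48/45 (PF3D7_1346700) rose from 0.654 ± 0.183 CPM in rings to 6.82 ± 0.755 in trophozoites. The list was not called in any comparison (camera adjusted p = 0.216, adjusted p = 0.842 and adjusted p = 0.193 in the order above, and adjusted p = 0.393, adjusted p = 0.844 and adjusted p = 0.393 with an estimated correlation).

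RNAPII peaks were numerous and mostly shallow at every stage. With N20 the authors' lists held 4816 peaks in rings, 5360 in trophozoites and 3498 in schizonts, and with CTD 3678, 2839 and 3221. Ser5-P gave 2932, 4290 and 3008 peaks and Ser2/5-P 2833, 3185 and 2936. Each list covered between 5.82% (trophozoite CTD) and 15.43% (trophozoite N20) of the effective genome size given in the file headers. The median fold enrichment over input, the authors' own value per peak, lay between 1.43 and 1.66 for all lists except ring Ser2/5-P at 2.07 and schizont Ser2/5-P at 1.80. The lists were called at a p of 0.05, and the share of peaks with a q below 0.01 ran from 0.2% (trophozoite CTD, 7 peaks) to 80.3% (ring Ser2/5-P, 2275 peaks). No difference in number between antibodies or stages was tested.

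Ser2/5-P lists held the tallest peaks. In rings 177 Ser2/5-P peaks (6.25% of the list) reached a fold enrichment of 5 or more, against 1 in trophozoites and 22 in schizonts, while the N20, CTD and Ser5-P lists held 1 such peak in all. The tallest ring peak lay on chromosome 3 from 368265 to 370530 (42.1-fold) and the tallest schizont peak on chromosome 3 from 30713 to 31250 (45-fold), and neither overlapped a peak of another antibody of its stage. In each stage 2 samples carry the Ser2/5-P label and the labels do not tie the list to either.

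**Figure D2:**
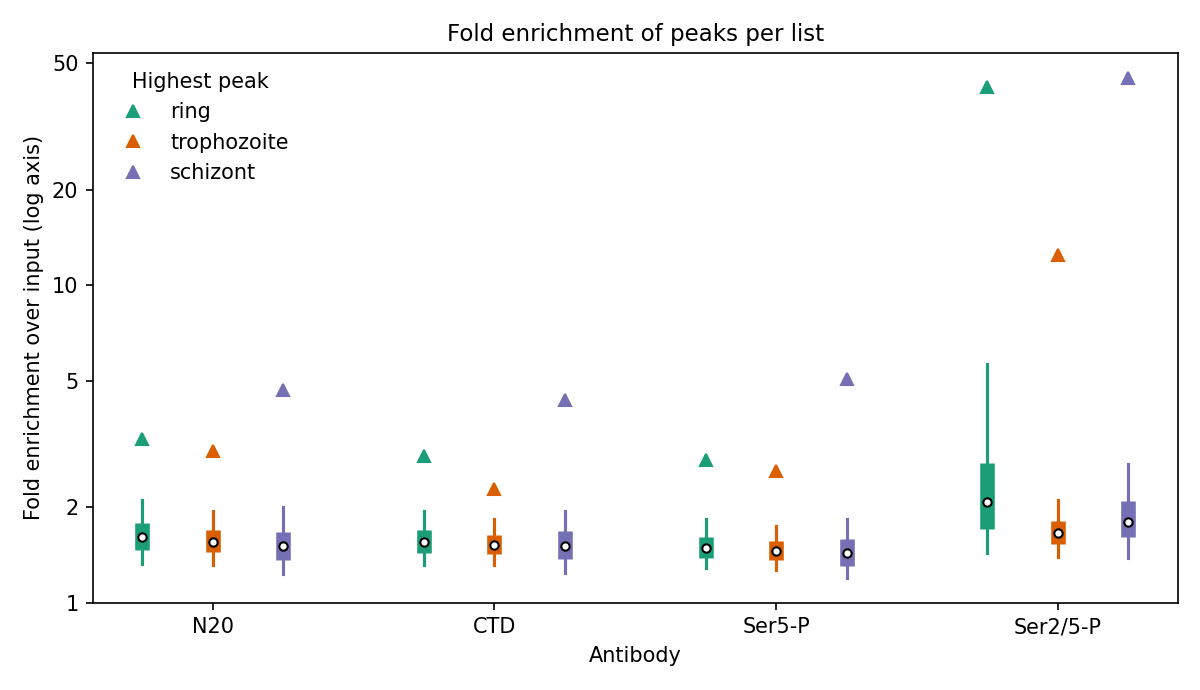
Fold enrichment over input (vertical log axis) of the peaks in each of 12 lists, by antibody and stage; thick bars span the middle of the distribution from the 25th to the 75th percentile, thin lines the 5th to the 95th, open circles are medians and triangles the highest peak. Most peaks lie near 1.5 to 2, and the Ser2/5-P lists reach 42.1 in rings and 45 in schizonts.

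Antibodies shared more peaks within a stage than random placement gave, and most in schizonts. Averaged over the 12 ordered antibody pairs of a stage, the share of peaks that overlapped a peak of the other antibody by at least 1 bp was 45.9% in rings, 48.3% in trophozoites and 63.4% in schizonts, against 21%, 20% and 20.7% for the same peaks placed at random within their chromosomes. Relative to random placement, schizonts stood highest with all peaks (3.06 times), while at q under 0.01 trophozoites (5.4 times) lay above schizonts (3.77 times). The trophozoite CTD list kept only 7 peaks at that q, which limits the trophozoite ratio. In schizonts 76.1% of Ser5-P peaks (Wilson 95% interval 74.5 to 77.6) overlapped a CTD peak and 74.4% (72.8 to 76.0) an N20 peak, whereas in rings 51.4% (49.6 to 53.2) of Ser5-P peaks overlapped CTD and 64.2% (62.4 to 65.9) overlapped N20. Ring Ser2/5-P peaks overlapped those of N20 in 54.9% of cases, 1.69 times the random share. All antibodies of a stage were called against input of the same depth, so their lists are not independent. Random placement, here and across stages, was uniform along each chromosome, including ends and stretches that held few or no peaks. Lists that share such gaps exceed it for that reason alone, so the ratios do not by themselves show shared RNAPII sites. Intervals cover counting error only.

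Across stages each antibody overlapped itself more than random placement gave. The mean share was 46.6% for N20, 28.4% for CTD, 33.7% for Ser5-P and 39.3% for Ser2/5-P, against 25.1%, 16.7%, 19.5% and 20.9% at random. The order of the antibodies turned at q under 0.01, where Ser2/5-P (27.4%) lay above N20 (23.6%) and Ser5-P (12.2%) below CTD (14.3%), and for the 1000 best peaks Ser2/5-P (25%) also lay above N20 (17.6%). Relative to random placement, Ser2/5-P (1.88 times) and N20 (1.86 times) were close with all peaks. At q under 0.01 these ratios were 3.86 for CTD, 2.6 for Ser5-P, 2.34 for Ser2/5-P and 1.97 for N20. CTD was thus highest, with only 7 peaks in its trophozoite list. For the 1000 best peaks the ratios were 2.31 for Ser2/5-P, 2.2 for N20, 1.85 for CTD and 1.82 for Ser5-P. Of ring N20 peaks, 64.8% (63.4 to 66.1) overlapped a trophozoite peak, 2.25 times the random share, while 31.5% (30.2 to 32.8) of ring N20 peaks overlapped a schizont peak, 1.62 times the random share. Overlap across stages was not particular to the same antibody. Ring N20 peaks overlapped schizont Ser2/5-P peaks in 34.4% of cases, above the share with schizont N20. Ring CTD peaks overlapped schizont N20 in 32.5% and schizont CTD in 28.4%. For ring Ser5-P these were 31.9% with N20 and 29.5% with Ser5-P. Ring Ser2/5-P went the other way, with 35.9% for schizont Ser2/5-P and 31.2% for N20. No random share was computed between different antibodies across stages. Lists of stages differ in depth and length, so these shares are descriptions of single lists.

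**Figure D3:**
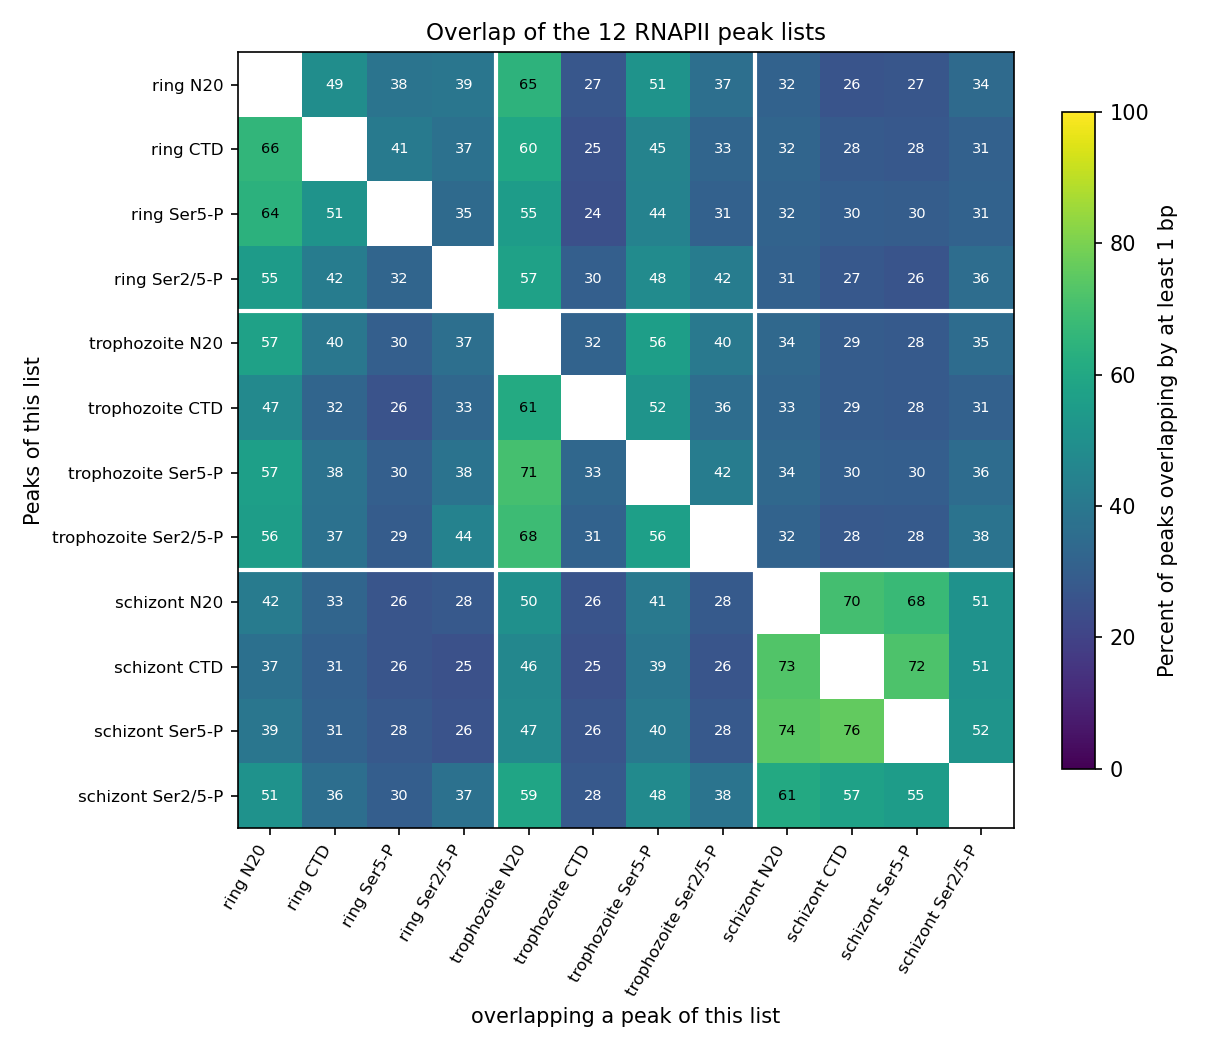
Percent of the peaks of each list (rows) that overlap a peak of another list (columns) by at least 1 bp, for 4 antibodies at 3 stages; white lines part the stages and the colour scale runs from 0 to 100%. The N20, CTD and Ser5-P lists of schizonts form the block of highest overlap, up to 76.1%.

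Regions where all 4 antibodies had a peak numbered 495 in rings, 563 in trophozoites and 1344 in schizonts, and 32, 50 and 160 of them touched no peak of either other stage. The all-antibody region with the tallest N20 peak in rings lay on chromosome 7 from 581324 to 581691 (N20 2.98-fold, CTD 1.94-fold, Ser5-P 1.82-fold, Ser2/5-P 1.98-fold). In trophozoites it lay on chromosome 9 from 1486912 to 1487244 (N20 2.90-fold) and in schizonts on chromosome 2 from 892044 to 892593 (N20 4.69-fold, Ser5-P 5.06-fold). Peaks of all 12 lists met in 2 regions, and no random expectation was computed for any of these region counts. Coordinates are those of the peak lists, for which no genome build is given in the sources used here, so peaks were not assigned to genes and the relation between RNAPII and mRNA per gene was not analysed here.

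The ends of chromosomes, where P. falciparum keeps most of its variant surface antigen genes, held few RNAPII peaks. Within 60 kb of position 1 or of the last peak end of a chromosome lay between 1.8% (ring Ser2/5-P, interval 1.3 to 2.3) and 3.6% (ring Ser5-P, interval 3.0 to 4.3) of the nuclear peaks of a list, against 6.9% to 7.3% at random placement. All 12 lists lay below their random value. The width of 60 kb was chosen after the lists were seen, and how well fragments map to these ends was not analysed here.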

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

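Scaling by library size alone and overlaps without tall peaks were chosen after the data were seen, and the other alternatives before. The number of changed genes in each comparison and across stages stayed within 1.5 times its main value in all alternatives run except 1, the 2-fold limit, with which schizont against trophozoite gave 2466 in place of 4003 because fewer genes meet it. With each library left out, trophozoite against ring gave 4081 to 4365 genes, schizont against trophozoite 3788 to 4085 and schizont against ring 4450 to 4603.

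The replicate numbers were not taken to pair the samples, since the deviations of libraries numbered 2 correlated by only 0.03 to 0.061 between stages, although those numbered 1 and 3 correlated by 0.275 to 0.594. In 8 of the 9 checks a library correlated best with its own number, a hint from the data and not the design. Of 36 ways to match libraries across stages, matching by number gave the highest mean correlation (0.281, highest other 0.197, exact test over these ways p = 0.0278). Replicates 1 and 3 differed most in every stage, so the low values for number 2 are weak evidence against pairing. The biological coefficient of variation was 0.102 with a replicate block and 0.152 without. With the replicate block the counts were 4405, 4286 and 4654 for the 3 comparisons in the order above, and no single-gene or list call examined was lost. Some list counts grew, with 1 exported gene rising from ring to schizont in place of 0. From trophozoite to schizont 16 replication genes rose in place of 14, and 2 gametocyte markers in place of 1. From ring to trophozoite 8 glycolysis genes fell in place of 7, and 1 gametocyte marker in place of 0.

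By library size alone the glycolysis median from ring to trophozoite turned from -0.41 to 0.21, LAP from -0.59 to 0.025 and PYK from -0.44 to 0.18, because the composition factors of the stages differ. With DESeq2 size factors the median of all genes moved by -0.24, 0.08 and -0.15. Of 1235 values of 95 single-gene results under alternatives, 1224 kept direction and call, 9 lost the call and 2 reversed; of 234 list values, 217 kept both. All 14 list calls were lost with an estimated correlation.

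Every mean overlap fell under stricter settings and stayed above random placement. The random share fell by a larger factor, so each overlap rose relative to random placement. Within schizonts it went from 3.06 times random to 3.77 at q under 0.01 and 4.01 for the 1000 best peaks. With 50% of the shorter peak it was 4.05, and for summits within 200 bp 5.02. The cause was not tested beyond fewer or smaller peaks. In the order rings, trophozoites, schizonts, then N20, CTD, Ser5-P and Ser2/5-P across stages, the percentages were 23.4, 24.3, 41.9, 23.6, 14.3, 12.2 and 27.4 at q under 0.01, and 23.2, 23.1, 38.1, 17.6, 12, 13.3 and 25 for the 1000 best peaks. They were 40.9, 40.7, 58.3, 38.9, 21.8, 26.3 and 34.4 with an overlap of 50% of the shorter peak, and 21.9, 24.3, 28.1, 24.6, 13.5, 15.0 and 17.3 for summits within 200 bp. Without peaks of 5-fold or more, rings gave 44.8 and Ser2/5-P across stages 37.5. At q under 0.01 trophozoite CTD keeps 7 peaks, which limits those values. Per-gene RNAPII alternatives were not run.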

Other observations

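All tests in this section were chosen or had their bounds written after results were seen, including the splits of the libraries and the peak-free stretches of chromosome 9. Counts of the real stage grouping were compared with other groupings of the libraries. For trophozoite against ring (4227 genes), schizont against trophozoite (4003) and schizont against ring (4540), the highest of the other 9 splits gave 0 genes, and 10 splits are too few for a share under 0.05. Across the 3 stages 1 of 100 splits, the real one, gave as many as 4834 genes, and the highest other gave 3255. Every other split mixed libraries of different stages, which widens the spread within its groups. The real grouping was therefore favoured from the start, and the splits do not exclude chance.

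A block of neighbouring genes near the right-hand end of chromosome 9 had almost no mRNA at any stage. From GDV1 (PF3D7_0935400) to PF3D7_0937200, all 19 genes had fewer than 10 counts summed over 9 libraries. Of these 17 had 0, among them REX1 (PF3D7_0935900), REX2 (PF3D7_0936000) and GEXP5 (PF3D7_0936600). The next gene inward, PF3D7_0935300, had 2679. Outward of the block, PF3D7_0937300 had 24 counts, PF3D7_0937400 had 211, PF3D7_0937700 had 56 and PF3D7_0937800 had 6036, so detected genes lay on both sides. All 19 have an entry in the count table, which argues against a gap in the authors' annotation, and the longest run of such genes in 1000 shuffles of gene order was 5, which argues against scattered genes that adjoin by chance but is not particular to this block, since runs of 8 genes (PF3D7_0701700 to PF3D7_0702400) and 6 genes (PF3D7_0220900 to PF3D7_0221400) were also longer. Over all 12 lists, chromosome 9 also had the longest stretch between peaks without any peak, 96259 bp from 1378343 to 1474601. The next longest were 58143 bp on chromosome 7 and 47518 bp on chromosome 2. Beyond the stretch on chromosome 9 peaks resumed, and the last ended at 1487313. A hypothesis is that the part of chromosome 9 with these genes may be missing from these parasites. Silent genes in DNA that is present cannot be told apart from this, because input coverage was not used. The build that would place the genes in the stretch is not given either. Gene IDs carry the prefix PF3D7, whereas the strain is labelled T996, and how well its reads map in this block was not analysed here.

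Tall Ser2/5-P peaks were mostly a feature of rings, with 177 peaks of 5-fold or more. A first test of low input coverage at these sites decides nothing, since 76.3% of them overlapped a peak of another antibody called against input of the same depth but so did 66.3% of the other ring Ser2/5-P peaks, and in schizonts 54.5% of the 22 tall peaks did, against 72.6% of the others. A second test, chosen after the first had been seen, argues against low input coverage as the whole cause, since the highest fold enrichment of those antibodies at these sites had a median of 1.74 and reached 2.49 at most, against a median of 6.80 for the tall peaks. Sampling noise of small libraries is left open by the overlap of tall peaks between rings and schizonts. The 5 tall ring peaks that overlapped a tall schizont peak lay well above the random mean of 0.87. They lay above the highest of 100 random placements, 4, by less than their counting spread. A low overlap could not have decided this either, since peaks particular to a stage would also fail to overlap. Tall ring peaks were 2184 bp wide at the median, against 791 bp for the whole list. The authors' q per peak was under 0.01 for 2275 of the 2833 peaks of this list (80.3%). That argues against sampling noise for most of the list. The share among the tall peaks alone was not counted, and the file headers say that no q was calculated. The ring list had the most Ser2/5-P fragments (1386117 against 1111950 in trophozoites and 1035895 in schizonts) and the shallowest input (1446678 fragments). DNA of another source and a stage difference in this phosphorylated form could each give the 177 peaks of a single ring list, and neither can be told apart without reads or a second list.

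The N20, CTD and Ser5-P lists of schizonts overlapped by 72.2% on average, against 51.7% in rings and 50.8% in trophozoites. Regions of low coverage in the shared input stay open, since the test of them decides nothing: Ser2/5-P, called against the same input, overlapped these lists by 0.755 times as much, and passed the bound of 0.5 in rings (0.775) and trophozoites (0.901) too. Deeper libraries cannot be told apart from stage, with mean depths of 3532669 fragments in schizonts, 2276469 in trophozoites and 2023766 in rings. Rings (51.7%) and trophozoites (50.8%) did not follow the order of depth, a small difference whose error was not estimated. A biological difference between stages was not tested.

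Peaks on sequences other than the 14 numbered chromosomes, taken as organellar, occurred in schizont lists only, 14 with N20, 4 with CTD and 4 with Ser5-P. These lists were also the deepest, with 3395324, 3234070 and 3968613 fragments, against 2739062 in the next, trophozoite Ser5-P. Schizont Ser2/5-P, with 1035895 fragments, had 0 such peaks, so depth cannot be told apart from stage.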
